A study of Mus musculus with 20 samples.

How the data were processed

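The labels state that RNA came from mouse embryonic stem cells kept without feeders in 2i and LIF, turned into EpiLCs, and aggregated with doxycycline in GK15 medium. Per the labels, total RNA was purified on columns, and biotin-labelled cRNA was made by the one-cycle protocol of the array's maker. The series description calls the 2 arrays of a group biological duplicates. The table deposited by the authors holds 1 value per probe set and array on a log2 scale; the base was inferred here, since base 2 puts the brightest values near the range of a 16-bit scanner. The normalization, the summarisation of probes and the software are not given in the sources used here, and the values were used as deposited. No detection calls were used here.

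The platform annotation gave 1 gene for 34945 probe sets and several for 932, and listed none for 9211. The 64 control probe sets of the array's maker were left out. Entrez gene identifiers of 34741 probe sets matched the reference gene table (assembly GRCm38.p6), which was used only for names and chromosomes; no symbol was updated. Probe sets were kept when their highest group mean was at or above the 40th percentile of all values, 3.95, which left 30406. Each gene was then represented by the probe set with the highest mean over all 20 arrays, which gave 14010 tested genes out of 18193 on the array. Names of expressed sequences and clones were left out of the named genes by a pattern of letter prefixes with at least 5 digits.

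A linear model with 10 group means was fitted to all 20 arrays by limma 3.58.1 in R 4.3.3, with 10 residual degrees of freedom and an empirical Bayes prior of 1.79 degrees of freedom. Comparisons were contrasts of that fit. P values are two-sided and adjusted by Benjamini-Hochberg over all genes of a contrast, and a call needs an adjusted p under 0.05 and a log2 change of at least 1. Tables were handled in Python 3.11.15 with pandas 2.3.3. With groups of 2, no other split of the samples can be counted and no test for an outlying sample applies. In every leave-one-out setting the lone array is assumed to vary like the other groups.

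Gene lists, written from general knowledge of the field, were tested by camera from limma with a preset correlation of 0.01 between genes, which asks whether a list shifts relative to the other genes. The 21 lists and 13 contrasts make 273 tests, adjusted together, the parental contrast included. With the preset correlation 58 passed an adjusted p of 0.05, and with an estimated correlation 0 passed, the lowest value being 0.0599. By fry, which tests whether a list's genes move one way on balance and compares them with no other genes, 85 passed. In 64 of the 273 tests a list's median, mean and camera direction were not all of one sign. A list member may owe its place to published work on these or similar cells, and the count adjusted over the list alone is then not independent evidence. The lists are the factors' own genes, early germ cells, later germ cells and meiosis, core pluripotency, naive pluripotency, epiblast and primed cells, DNA methylation, histone modifiers, primitive streak and mesoderm, Hox genes, endoderm, neural genes, trophectoderm and surface ectoderm, BMP, WNT, FGF and ERK, cell cycle, p53 and stress, hypoxia and glycolysis, fibroblasts or feeders, and the 2-cell-like state.

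The named genes are the 8 largest changes in each direction for the main contrasts, 4 for the others, called members of the lists, and the factors. Other names, such as those of genes shared between lines or specific to the 3-factor line, were chosen after their values were seen. The groups, the comparisons, the lists, the thresholds, the naming rule and the alternatives were chosen before the data were examined, and the main model was not changed afterwards. A self-test added known changes to simulated data of the same size and spread. For the 3-factor contrast it called 60% of genes at a log2 change of 1, 82.5% at 1.5 and 100% at 3. There were 3 false calls among the unchanged genes. For the Tfap2c contrast the shares were 45%, 87.5% and 100%, with 2 false calls. A simulated change of 1 lies at the limit for a call, so the shares at 1 reflect that limit as well as the noise.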

Results

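RNA was measured on 20 microarrays, 2 in each of 10 groups, in mouse embryonic stem cell derivatives that carry doxycycline-inducible transgenes. The groups crossed 5 male cell lines with 2 stages. The parental line carries the doxycycline-responsive activator and fluorescent reporters for Blimp1 and stella, 2 genes of the early germ line. The other lines each carry, in addition, a transgene for Blimp1 (the protein of Prdm1), for Prdm14, for Tfap2c (AP2γ), or for all 3 of these transcription factors. The stages were epiblast-like cells (EpiLCs, a culture state close to the early post-implantation epiblast) before doxycycline, and aggregates after 24 h with doxycycline and without added cytokines, called day 1 here. The purpose of the design is to ask which genes of the germ-cell programme the factors turn on or off, together and singly. Each line is a single clone, so factor and clone cannot be told apart, and no aggregates without doxycycline were among the samples. Values were on a log2 scale from 0 to 13.83, array medians lay between 4.60 and 4.86, and 639 to 810 values per array were at 0. Replicate arrays correlated across all probe sets at Pearson r of 0.9887 to 0.9919, and probe sets are not independent replicates. The number of arrays, 2 per group, limits the precision. A gene was called when its Benjamini-Hochberg adjusted p from limma was under 0.05 and its log2 change was at least 1 in size, out of 14010 genes tested. Errors of log2 changes are limma standard errors (SE). Where a group's mean lay below the filter level of 3.95, a change is measured from near background and its size is approximate, and such genes are named in each paragraph that gives sizes.

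The parental line on day 1 against its EpiLCs shows what aggregation, medium and doxycycline do without a transgene. Trh, which encodes a neuropeptide precursor also made in the epiblast, rose by 6.25 ± 0.21 (SE, adjusted p = 1.28e-08). Nkx1-2 and Fgf8, genes of the caudal epiblast and primitive streak, rose by 4.21 ± 0.26 (adjusted p = 3.65e-07) and 3.72 ± 0.44 (adjusted p = 4.57e-05). The pluripotency genes Nanog and Klf2 rose by 2.56 ± 0.12 (adjusted p = 4.96e-08) and 3.39 ± 0.28 (adjusted p = 3.24e-06), and the signalling ligand Nodal by 1.38 ± 0.14 (adjusted p = 1.39e-05). Frem2, Zeb2, Stmn4, Sp8 and Greb1l rose by between 3.57 and 4.65. The EpiLC means of Nkx1-2, Fgf8, Frem2, Zeb2, Stmn4 and Sp8 lay below the filter level. Among the genes that fell were Dnmt3l, a cofactor of de novo DNA methylation, by 3.50 ± 0.27 (adjusted p = 1.91e-06), and Hormad1, a meiotic chromosome protein, by 3.63 ± 0.30 (adjusted p = 3.11e-06). Rpl39l fell by 3.98 ± 0.23 (adjusted p = 2.57e-07), and Morc1, which silences transposons in germ cells, by 3.75 (adjusted p = 1.19e-06).

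Later germ cell and hypoxia genes moved down as lists in the parental line. Of 17 later germ cell and meiosis genes, 9 fell and 0 rose, with Dazl at −1.52, Stag3 at −1.82 and Tex19.1 at −1.72 (median −1.13, camera adjusted p = 8.36e-06; adjusted p = 0.129 with an estimated correlation). Of 17 hypoxia and glycolysis genes, 10 fell, including Bnip3 at −2.20 and Pdk1 at −1.80, and Slc2a3 rose (median −1.22, camera adjusted p = 4.24e-07; adjusted p = 0.312 with an estimated correlation). Among 12 DNA methylation genes, 4 fell and 0 rose (camera adjusted p = 0.000699; adjusted p = 0.0599 with an estimated correlation). Naive pluripotency genes mark the ground state of embryonic stem cells. Of 19 tested, 1 rose, Klf2, and 5 fell, including Tcl1 at −1.57 and Zfp42 at −1.57 (camera adjusted p = 0.00252; adjusted p = 0.161 with an estimated correlation). Of 14 core pluripotency genes 1 rose and 5 fell, with Fgf4 at −1.59 and Gdf3 at −1.48 (camera adjusted p = 0.034; adjusted p = 0.355 with an estimated correlation). Among 19 early germ cell genes 1 rose and 3 fell, Dppa3 (stella) by 1.21 ± 0.28 (adjusted p = 0.00505), a call that ended under treat against a log2 change of 0.5; the list's median was 0.20 and its mean −0.04 (camera adjusted p = 0.978). Prdm1 and Tfap2c themselves changed by 0.67 and 0.65, below the limit for a call. Tcl1 lay below the filter level on day 1.

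The other lists passed no camera test in this comparison. Primitive streak and mesoderm genes had 3 of 20 rising, Wnt8a by 2.83 from below the filter level, with a median of −0.06, a mean of 0.40 and camera adjusted p = 0.995. Epiblast and primed genes had 2 of 20 rising and 2 falling (adjusted p = 0.978), endoderm genes 2 of 12 rising and 1 falling (adjusted p = 0.918), and neural genes 2 of 13 rising and 1 falling (adjusted p = 0.902). Of 16 trophectoderm and surface ectoderm genes 2 rose, Krt8 by 1.92, and 2 fell (adjusted p = 0.873). FGF and ERK genes had 3 of 16 falling (adjusted p = 0.509), WNT targets 1 of 8 rising (adjusted p = 0.968), p53 and stress genes 1 of 17 rising (adjusted p = 0.0815) and fibroblast or feeder genes 1 of 10 rising, Tagln by 2.86 (adjusted p = 0.83). No member was called among 17 histone modifiers, 11 Hox genes, 11 BMP targets, 24 cell cycle genes, 3 genes of the 2-cell-like state and the 3 factors' own genes (adjusted p = 0.254, 0.861, 0.197, 0.357, 0.799 and 0.321). Adjusted over the list alone, the counts were the same in every list but the trophectoderm one, where 1 gene rose. Over all genes 556 rose and 365 fell, 921 in total, out of 6024 with an unadjusted p under 0.05. The probes for 18S ribosomal RNA read 11.54 ± 0.36 in parental EpiLCs and 12.03 on day 1 (SD, n = 2), a difference between the stages in a quality probe.

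The factors' own genes were read first, since the lines differ in which transgene they carry. Tfap2c, at the brightest of its 3 probe sets, stood at 6.34 ± 0.06 (SD, n = 2) in parental day 1 aggregates and at 11.57 ± 0.02 in the line with all 3 factors. It stood at 9.60 ± 0.30 in the Blimp1 line, 10.81 ± 0.15 in the Prdm14 line and 5.94 ± 0.20 in the Tfap2c line. Both other Tfap2c probe sets showed the same order, with changes of 5.12, 2.77, 4.20 and −1.13 at the first and 5.04, 2.64, 3.97 and −0.61 at the next for the 3-factor, Blimp1, Prdm14 and Tfap2c lines. At both of them the parental and Tfap2c-line means on day 1 lay below the filter level, so these sizes are approximate. Prdm1 stood at 4.96 ± 0.08 in parental aggregates, 8.67 ± 0.06 with all 3 factors, 6.36 ± 0.16 in the Blimp1 line, 7.31 ± 0.11 in the Prdm14 line and 5.01 ± 0.24 in the Tfap2c line. Prdm14 has 1 dim probe set, whose day 1 changes lay between −0.13 and 0.41 with an SE of 1.15, and none was called (limma adjusted p from 0.847 to 0.992). Whether any of these probe sets reads a transgene is not given in the sources used here, so they check no transgene.

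The line with all 3 factors against the parental line on day 1 asks what the factors do together. Dppa3, an early germ cell gene whose reporter the cells carry, rose from 6.10 ± 0.18 (SD, n = 2) to 11.46 ± 0.07, by 5.36 ± 0.28 (SE, limma adjusted p = 4.39e-08). Tcl1 and Nr0b1, which belong to naive pluripotency, rose by 5.08 ± 0.23 (adjusted p = 1.48e-08) and 3.67 ± 0.17. Prdm1 rose by 3.72 ± 0.13 (adjusted p = 2.23e-09) and Tfap2c by 5.23 ± 0.13 (adjusted p = 2.44e-10), with Ifitm3, a membrane protein of early germ cells, up by 3.47 ± 0.11. Pou3f1, a transcription factor of the primed epiblast, fell from 11.68 to 6.81, by 4.88 ± 0.11 (adjusted p = 1.03e-10). The de novo DNA methyltransferase Dnmt3b fell from 13.21 to 9.87, by 3.34 ± 0.10 (adjusted p = 9.02e-10). The neural gene Sox1 fell by 4.02 ± 0.24 (adjusted p = 1.61e-07). The kinase Pim2 fell by 5.07 ± 0.10 (adjusted p = 3.71e-11), and Nt5e, Pcdh8, Podxl, Sema6a, Cxcl12 and Rtn4rl1 fell by between 4.05 and 5.05. Hesx1, Lrrc31, Epas1, Adgrg6 and Lrrc34 rose by between 4.12 and 4.66. Parental means of Tcl1, Hesx1, Lrrc31, Adgrg6 and Lrrc34, and 3-factor means of Sox1, Nt5e, Pcdh8, Sema6a and Rtn4rl1, lay below the filter level.

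**Figure D1:**
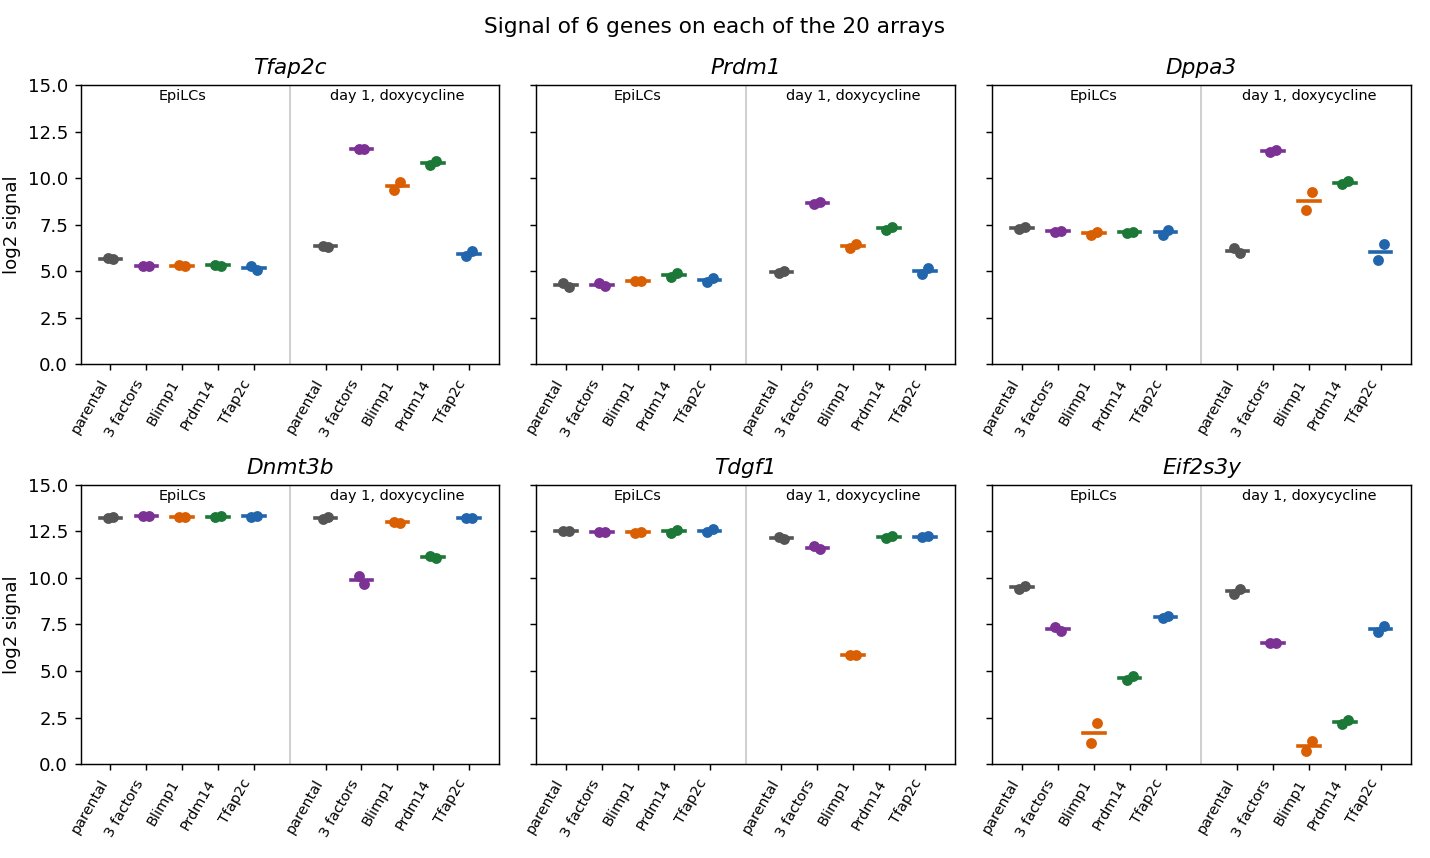
Log2 signal of 6 genes in each of the 20 arrays, by line and stage; each dot is an array and each bar the mean of 2. Dppa3 reaches 11.46 on day 1 with all 3 factors and 6.10 in the parental line, while Dnmt3b stands at 9.87 and 13.21.

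Germ-line and naive pluripotency genes rose as lists in this line and epiblast genes fell. Of 19 early germ cell genes 10 rose and 1 fell, or 11 and 1 adjusted over the list alone (median 1.47, camera adjusted p = 5.16e-08; adjusted p = 0.0697 with an estimated correlation). Of 19 naive genes 12 rose and 2 fell, with Tfcp2l1 up by 3.96 ± 0.28 and Fbxo15 up by 3.00 (median 1.59, camera adjusted p = 3.26e-07; adjusted p = 0.0599 with an estimated correlation). Of 14 core pluripotency genes 3 rose, Sox2 by 1.84 ± 0.09, Zfp296 by 2.44 and Gdf3 by 2.10 (camera adjusted p = 0.00522; adjusted p = 0.222 with an estimated correlation). Of 20 epiblast and primed genes 11 fell, Foxd3 by 3.01, and 2 rose, Lef1 by 2.02 and Etv4 by 1.82 (median −1.31, camera adjusted p = 4.96e-05; adjusted p = 0.119 with an estimated correlation). Later germ cell and meiosis genes had 3 of 17 rising, Hormad1, Stk31 and Dazl, by 1.43, 1.07 and 1.06 (camera adjusted p = 0.0148; adjusted p = 0.399 with an estimated correlation). Of 17 p53 and stress genes 4 fell, including Atf3 by 1.43 (camera adjusted p = 0.0406; adjusted p = 0.355 with an estimated correlation). The factors' own genes, of which Prdm1 and Tfap2c rose, gave camera adjusted p = 0.00131 and adjusted p = 0.125 with an estimated correlation. These probe sets may read the line's transgenes, so this shift is by itself no evidence of a response.

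Other lists of the 3-factor line had called members that went both ways or did not shift as a list. Among neural genes Sox1, Sox3 and Nes were among 5 that fell and Lhx5 rose, with 2 rising and 5 falling adjusted over the list alone (adjusted p = 0.192). Among FGF and ERK genes Dusp4 rose by 3.37, Fgfr2 by 1.85 and Etv4 by 1.82 (adjusted p = 0.0563). Among hypoxia genes Ndrg1 rose by 2.77 and 4 fell, Ldha by 1.54, Hk2 by 1.45 and Slc2a1 by 1.30 among them (adjusted p = 0.465). Id4 rose by 3.87 and Smad6 fell by 2.27, to below the filter level, among BMP targets (adjusted p = 0.263), and Lef1 rose and Sp8 fell among WNT targets (adjusted p = 0.981). DNA methylation genes had 2 rising, Gadd45a by 1.34 and Apobec1 by 1.06, and 2 falling, Dnmt3b and Dnmt3a, the latter by 1.27 ± 0.26 (adjusted p = 0.824 for the list). Among histone modifiers Kdm3a rose by 1.03 and Kdm6b fell by 1.28 (adjusted p = 0.799). Krt18 fell by 1.76 and Krt8 by 1.26 among trophectoderm genes (adjusted p = 0.299), and Thy1 by 3.04 and Dcn by 1.07 among feeder genes (adjusted p = 0.635). Rspo3 rose and Mixl1 fell among mesoderm genes (adjusted p = 0.843), Foxa1 and Foxa2 fell among endoderm genes, Foxa1 with both means below the filter level (adjusted p = 0.941), and Hoxd13 fell among Hox genes (adjusted p = 0.875). No cell cycle or 2-cell-like gene was called (adjusted p = 0.948 and 0.828), and adjusted over the list alone the counts of the lists not singled out were the same. In all, 389 genes rose and 539 fell, 928 in total, out of 5136 with an unadjusted p under 0.05. The calls of Dnmt3a, Dazl, Stk31, Nes and Kdm6b ended when all probe sets of a gene were averaged, those of Mixl1, Foxa2, Hoxd13, Lhx5 and Smad6 when only the 4 arrays compared were fitted, and those of Dcn, Hormad1, Rspo3 and Foxa1 under treat. Without parental day 1 replicate 1 Apobec1, Foxa2 and Mixl1 were not called, without parental replicate 2 Foxa1, Foxa2, Hoxd13, Kdm3a, Lhx5 and Mixl1, without the line's replicate 1 Hoxd13, Kdm3a and Stk31, and without its replicate 2 Apobec1, Dazl, Foxa2 and Mixl1.

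The Prdm14 line asks what this factor does alone, and naive pluripotency genes rose in it. Nr0b1 rose by 4.38 ± 0.17 (SE, limma adjusted p = 7.41e-09), Tcl1 by 4.63 and Tcf15, a gene linked to priming for differentiation, by 3.82. Epas1, which encodes a hypoxia-inducible factor subunit, rose from 5.45 to 10.41, by 4.97 ± 0.15 (adjusted p = 9.6e-10). Tfap2c rose by 4.47 ± 0.13 (adjusted p = 9.6e-10), Prdm1 by 2.36 ± 0.13 (adjusted p = 1.22e-07) and Dppa3 by 3.65 ± 0.28 (adjusted p = 1.52e-06). Pou3f1 fell by 3.31 ± 0.11, Dnmt3b by 2.07 ± 0.10 (adjusted p = 5.23e-08) and Pim2 by 4.35 ± 0.10 (adjusted p = 2.24e-10). Lrrc31, Gprc5a and Bnc2 rose by 4.51, 3.93 and 3.69, and Nt5e, Lzts1, Hs6st2, Efemp1 and Cxcl12 fell by between 3.94 and 4.90. The Y-linked genes Eif2s3y and Uty were lower by 6.99 and 4.21 and were already low in this line's EpiLCs. Parental means of Tcl1, Lrrc31 and Gprc5a, and means of Nt5e, Lzts1, Efemp1 and Eif2s3y in this line, lay below the filter level.

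Most of the lists that shifted in the 3-factor line did so in the Prdm14 line as well. Of 19 naive genes 13 rose and 1, Socs3, fell by 2.91 to below the filter level (median 1.56, camera adjusted p = 2.13e-10; adjusted p = 0.0599 with an estimated correlation). Of 19 early germ cell genes 7 rose, Ifitm3 by 3.10, and Pdpn fell by 2.56 (median 0.82, camera adjusted p = 1.03e-07; adjusted p = 0.0697 with an estimated correlation). Core pluripotency had 4 of 14 rising, Zfp296, Sox2, Gdf3 and Fgf4, by 2.14, 1.79, 1.23 and 1.02 (camera adjusted p = 9.65e-05; adjusted p = 0.113 with an estimated correlation). Of 16 FGF and ERK genes 5 rose, including Dusp4 by 2.43, Fgfr2 by 1.45 and Myc by 1.36 ± 0.11, and 1 fell (camera adjusted p = 0.00107; adjusted p = 0.0599 with an estimated correlation). Epiblast genes had 8 of 20 falling and 2 rising (median −0.49, camera adjusted p = 0.014; adjusted p = 0.326 with an estimated correlation). Meiosis genes had 2 rising, Hormad1 by 1.62 and Tex19.1 by 1.14 (camera adjusted p = 0.0039; adjusted p = 0.336 with an estimated correlation), and the factors' own genes 2 (camera adjusted p = 0.00122; adjusted p = 0.125 with an estimated correlation). Ndrg1 rose by 3.31 and 3 hypoxia genes fell (adjusted p = 0.828), and Sox1, down by 2.53 to below the filter level, was 1 of 3 neural genes that fell (adjusted p = 0.722). The remaining lists passed no camera test in this line. In all, 305 genes rose and 448 fell, 753 in total, out of 4785 with an unadjusted p under 0.05. Fgf4 was no longer called without parental day 1 replicate 1, or when arrays were centred on their medians or probe sets averaged.

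The Blimp1 line on day 1 had lower levels of several epiblast genes than the parental line, and higher levels of several early germ cell genes. Tdgf1, which encodes the Nodal coreceptor Cripto, fell from 12.13 to 5.87, by 6.26 ± 0.08 (SE, limma adjusted p = 1.73e-13), and Nodal fell by 2.88 ± 0.14 (adjusted p = 1.61e-07). The growth regulator Myc, a gene that Blimp1 represses in B cells, fell by 2.62 ± 0.11 (adjusted p = 5.03e-08). Foxd4 rose from 4.08 to 9.72, by 5.65 ± 0.33 (adjusted p = 6.31e-07). Ifitm1, expressed at the surface of early germ cells and mesoderm, rose by 3.31 ± 0.13 (adjusted p = 3.08e-08), and Tfap2c by 3.26 ± 0.13 (adjusted p = 3.27e-08). Prdm1 rose by 1.41 ± 0.13 (adjusted p = 2.48e-05). Dppa3 rose by 2.68 ± 0.28 (adjusted p = 6.01e-05) to 8.78 ± 0.67 (SD, n = 2). Gprc5a, Pdzk1, Aldh1a2, Fbxo15 and Nrk rose by between 2.72 and 4.96, and Pcdh8, Chst15 and Has2 fell by between 3.35 and 3.93. Eif2s3y, Erdr1, Mid1 and Uty were lower by between 6.17 and 8.29 and were already low before doxycycline. Parental means of Gprc5a, Pdzk1 and Aldh1a2, and means of Pcdh8, Chst15, Eif2s3y, Mid1 and Uty in this line, lay below the filter level.

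Epiblast genes fell as a list in the Blimp1 line and early germ cell genes rose. Of 20 epiblast genes 7 fell, Dnmt3a by 2.19 ± 0.26 and Foxd3 by 2.06 among them, and Lef1 rose by 1.63 (median −0.58, camera adjusted p = 3.33e-08; adjusted p = 0.0599 with an estimated correlation). Of 19 early germ cell genes 8 rose, Ifitm3 by 1.79 (median 0.39, camera adjusted p = 0.000432; adjusted p = 0.193 with an estimated correlation); 7 rose after quantile normalization and 6 after centring. Stress genes had 4 of 17 falling, Chac1 by 1.84 and Trib3 by 1.64 (median −0.46, camera adjusted p = 7.49e-06; adjusted p = 0.0697 with an estimated correlation). Core pluripotency shifted down, although Sox2 rose by 1.13, with 2 of 14 falling, Tdgf1 and Fgf4 (camera adjusted p = 0.00884; adjusted p = 0.254 with an estimated correlation). Naive genes had 4 of 19 rising, including Tcl1 by 2.34, from below the filter level, and Tfcp2l1 by 2.04, and 1 falling (adjusted p = 0.0814). The factors' own genes had 2 of 3 rising (camera adjusted p = 0.00244, and adjusted p = 0.142 with an estimated correlation), of which Prdm1 may be read from the line's transgene. Id2 rose by 2.31 and Id4 by 1.56 among BMP targets, where Smad7 fell by 2.11 and Id3 by 1.06 (adjusted p = 0.828). Wnt8a and Fgf8 fell by 2.37 and 2.71 to below the filter level, while Dll1 rose by 1.53 among mesoderm genes (adjusted p = 0.875 for the list), and the remaining lists passed no camera test. Adjusted over the list alone, the counts of called members given here for the Blimp1 and Prdm14 lines were the same.

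In the Blimp1 line 196 genes rose and 167 fell, 363 in total, out of 4208 with an unadjusted p under 0.05. The balance between directions depends on scaling, since 54.0% of calls were rises as deposited and 42.5% after centring each array on its median. With only the 4 arrays compared, 142 genes were called, and Dppa3, Tcl1, Tfcp2l1, Aldh1a2, Fgf8, Dnmt3a, Chac1, Trib3, Wnt8a, Id3 and Id4 were no longer among them. Fgf4 was not called when probe sets were averaged, Wnt8a not without parental day 1 replicate 1, and Id3 not without Blimp1 day 1 replicate 1 or parental replicate 2.

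**Figure D2:**
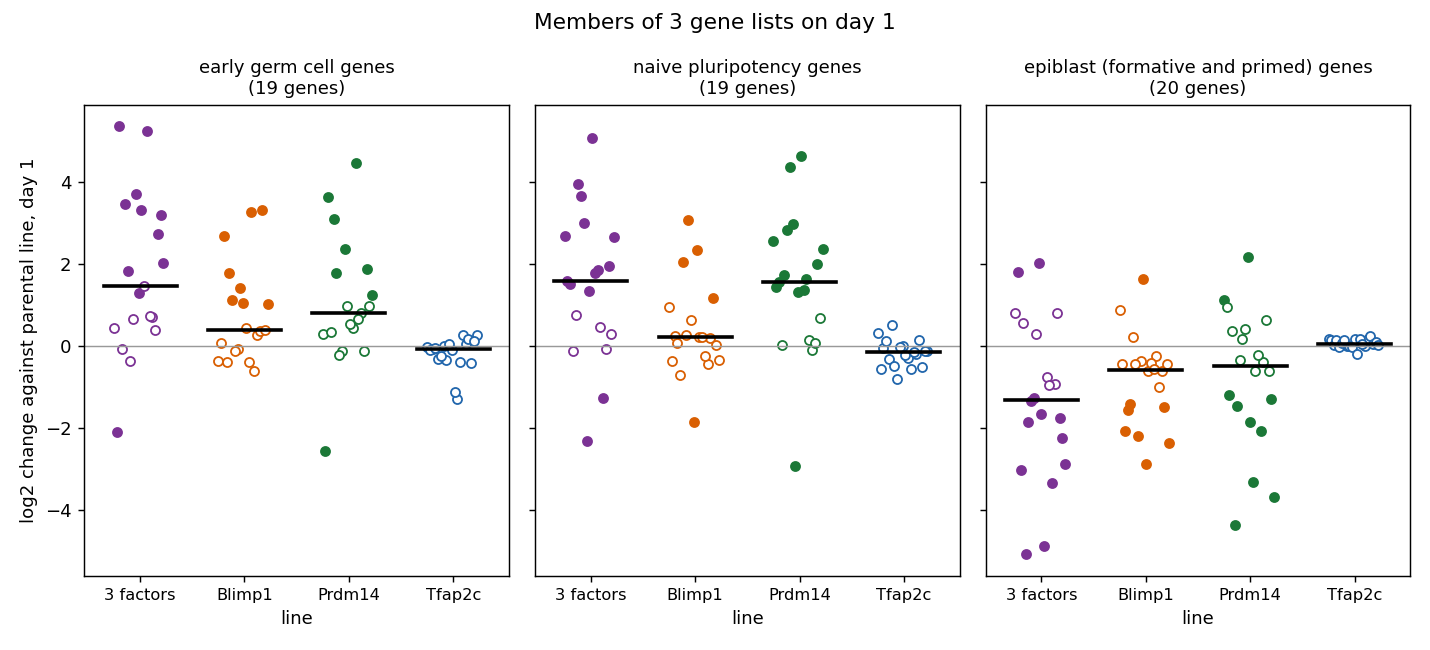
Log2 change on day 1 against the parental line for each member of chosen gene lists, by line; each dot is a gene, filled where it was called, and the black line is the median. Early germ cell genes have medians of 1.47, 0.39 and 0.82 in the 3-factor, Blimp1 and Prdm14 lines.

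The Tfap2c line asks the same of the remaining factor, and few genes differed in it on day 1. Dppa3 changed by −0.08 ± 0.28 (SE, limma adjusted p = 0.989), Nr0b1 by −0.49 (adjusted p = 0.612), Dnmt3b by 0.01 (adjusted p = 0.998), Pim2 by −0.03 (adjusted p = 0.987) and Tfap2c itself by −0.40 ± 0.13 (adjusted p = 0.581), none of them a call. No gene rose, and 4 fell. H13, a signal peptide peptidase, fell by 1.72 ± 0.14 and Gnptab, an enzyme of lysosomal sorting, by 1.02 ± 0.08 (adjusted p = 0.000292 for each). Eif2s3y fell by 2.02 ± 0.28 and Zfp936 by 1.08 ± 0.15 (adjusted p = 0.0235 for each). H13 and Gnptab were called lower before doxycycline as well, and Eif2s3y was then lower by 1.59 ± 0.28 without a call (adjusted p = 0.14). At an unadjusted p under 0.05 there were 927 genes. All 21 lists had 0 called members, also adjusted over the list alone. By camera the meiosis list shifted down (adjusted p = 0.000417; adjusted p = 0.212 with an estimated correlation), core pluripotency down (adjusted p = 0.002; adjusted p = 0.179 with an estimated correlation) and the epiblast list up (adjusted p = 0.0325; adjusted p = 0.389 with an estimated correlation). The count was 1 without parental day 1 replicate 1, 12 without parental replicate 2 and 2 without Tfap2c day 1 replicate 2. H13 was called whichever array was left out, unlike the other 3 genes, but not when probe sets were averaged or only 4 arrays fitted.

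Before doxycycline the lines differ by clone and by the transgene they carry, whose expression without doxycycline was not tested. In the Blimp1 line 5 of the 11 calls, with the largest measured changes, were sex-linked genes. Its EpiLCs were lower in Eif2s3y by 7.81 ± 0.28 (SE, limma adjusted p = 2.99e-08), in Uty by 5.62 ± 0.24 (adjusted p = 9.5e-08) and in Uba1y by 4.21 (adjusted p = 4.44e-08), all on the Y chromosome. Erdr1 and Mid1, at the end of the sex chromosomes, were lower by 8.20 ± 0.11 (adjusted p = 7.93e-13) and 7.07 ± 0.59 (adjusted p = 0.000132). The junction gene Jam2 was lower by 3.12 (adjusted p = 3.5e-05) and lay 1.86 below the parental line on day 1. The Blimp1-line means of Eif2s3y, Uty, Uba1y, Mid1 and Jam2 lay below the filter level. In Prdm14-line EpiLCs Eif2s3y, Uty and Uba1y were lower by 4.88, 3.80 and 1.71 (adjusted p = 1.11e-05, 1.11e-05 and 0.00063), and Slc38a4, an amino acid transporter, by 1.47 (adjusted p = 0.00063). The 3-factor line had Nnat higher by 1.22 (adjusted p = 0.0384) and Eif2s3y lower by 2.23 (adjusted p = 0.0166), with Uty at −0.12 and not called. The Tfap2c line had H13 and Gnptab lower by 1.61 and 1.05 (adjusted p = 0.000621 and 0.000287). Ufsp2 was lower than in the parental line in all 4 lines, by 0.88, 0.76, 1.08 and 1.21 in the 3-factor, Blimp1, Prdm14 and Tfap2c lines (adjusted p = 0.000307, 0.000194, 1.11e-05 and 8.36e-06), past the limit for a call in the Prdm14 and Tfap2c lines.

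Called genes in EpiLCs numbered 2 in the 3-factor line, 11 in the Blimp1 line, 5 in the Prdm14 line and 4 in the Tfap2c line, out of 1046, 1516, 819 and 1079 with an unadjusted p under 0.05. Hypoxia genes shifted down by camera in the 3-factor, Blimp1 and Tfap2c lines (adjusted p = 0.00583, 5.95e-07 and 0.00252; adjusted p = 0.608, 0.326 and 0.584 with an estimated correlation). In the Blimp1 line the naive, DNA methylation and Hox lists passed as well (adjusted p = 0.015, 0.0184 and 0.0369; adjusted p = 0.254, 0.125 and 0.193 with an estimated correlation). In the Prdm14 line the naive and core lists shifted up and the meiosis list down (adjusted p = 0.00289, 0.014 and 0.0331; adjusted p = 0.165, 0.291 and 0.455 with an estimated correlation). These counts rest on single arrays in part. For the 3-factor line the count was 10 without parental EpiLC replicate 1, and 1 and 6 without its own replicates 1 and 2. The Blimp1 line had 26 without parental replicate 2. For the Prdm14 line the count was 16 without parental replicate 1 and 8 without its own replicate 2, and for the Tfap2c line 9 without parental replicate 1 and 9 without its own replicate 2, where Gnptab was not called. In the 3-factor line Nnat was not called without parental replicate 1 or either of the line's own, nor Eif2s3y without parental replicate 2 or either of the line's own. With only the 4 arrays compared, Eif2s3y and Uty were not called in the Blimp1 line, nor Uty, Uba1y and Slc38a4 in the Prdm14 line.

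**Figure D3:**
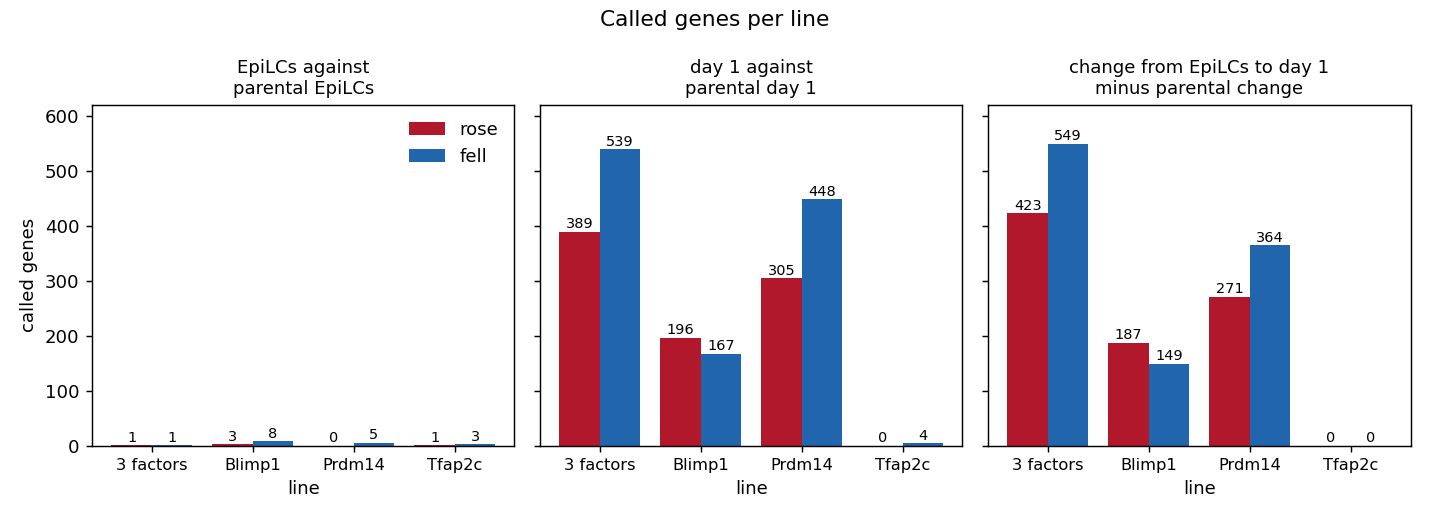
Number of genes that rose (red) and fell (blue) in each line against the parental line in EpiLCs, on day 1, and in the change from EpiLCs to day 1 minus that of the parental line; bars start at 0. The 3-factor line has 389 rises and 539 falls on day 1 against 1 and 1 in EpiLCs.

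Subtracting each line's EpiLC difference asks how much of the day 1 difference appeared after EpiLCs. This contrast uses 4 groups and has a larger SE, so a call lost in it is not by itself a sign of a clone effect. Of the 928 day 1 calls in the 3-factor line, 778 (83.8%) were also called in this difference of changes, among them Dppa3, Tcl1, Pou3f1 and Pim2. The Prdm14 line kept 547 of 753 (72.6%), including Epas1 and Nr0b1, and the Blimp1 line 227 of 363 (62.5%), including Foxd4 and Tdgf1. The sign was the same for 927, 751 and 358 of the day 1 calls of the 3-factor, Prdm14 and Blimp1 lines, and 1, 3 and 8 of them had been called in the same direction before doxycycline. The difference of changes contains the day 1 difference by which these genes were picked. Agreement in sign is therefore largely built in and is no separate evidence. The Tfap2c line had no call, by limma, with 652 genes at an unadjusted p under 0.05, and 0 of its 4 day 1 calls were kept; 2 of the 4, H13 and Gnptab, had been called in the same direction before doxycycline. As lists, early germ cell genes shifted up in the 3-factor, Blimp1 and Prdm14 lines (camera adjusted p = 4.72e-08, 0.000836 and 5.14e-07; adjusted p = 0.0697, 0.212 and 0.0904 with an estimated correlation), with 11, 7 and 8 members rising, or 12, 7 and 8 adjusted over the list alone. Naive genes shifted up with 11, 5 and 10 rising, or 11, 5 and 11 adjusted over the list alone (camera adjusted p = 3.26e-07, 0.00122 and 7.15e-09; adjusted p = 0.0599, 0.139 and 0.0599 with an estimated correlation). Epiblast genes shifted down with 12, 9 and 8 falling (camera adjusted p = 9.41e-06, 3.33e-08 and 0.0039; adjusted p = 0.0935, 0.0599 and 0.24 with an estimated correlation). In the Blimp1 line 7 stress genes fell (camera adjusted p = 5e-07; adjusted p = 0.0599 with an estimated correlation). Core pluripotency shifted up in the 3-factor and Prdm14 lines and down in the Blimp1 line (camera adjusted p = 0.0229, 0.000841 and 0.00122; adjusted p = 0.332, 0.149 and 0.161 with an estimated correlation). Meiosis genes shifted up in the 3-factor and Prdm14 lines (adjusted p = 0.022 and 0.000281; adjusted p = 0.423 and 0.197 with an estimated correlation), as did FGF and ERK genes (adjusted p = 0.0394 and 0.0033; adjusted p = 0.16 and 0.0697 with an estimated correlation). In the Tfap2c line core pluripotency shifted down and hypoxia genes up (adjusted p = 7.06e-06 and 0.04; adjusted p = 0.0697 and 0.742 with an estimated correlation).

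The lines' day 1 responses were then set side by side. Of the calls of the Prdm14 line 562, or 74.6%, were called in the same direction in the 3-factor line, 223 rising and 339 falling, where independent lists would share 8.47 and 17.24. The gene Upp1 was the only 1 called in opposite directions. The Blimp1 line shared 162 calls with the 3-factor line, 44.6% of its own, and 19 were opposite. It shared 112 with the Prdm14 line, and 25 were opposite, among them Myc, Fgf4 and Wt1. In all 3 lines 58 genes rose, including Tcl1, Tfap2c, Dppa3, Gprc5a, Bnc2, Id4, Arid5b and Ifitm3, and 38 fell, including Nt5e, Pim2, Pcdh8, Hs6st2, Has2, Fst, Trh, Wnt8a and Foxd3. The 38 also count Eif2s3y, which was low in these lines before doxycycline. The changes of all 14010 genes correlated at r of 0.825 between the 3-factor and Prdm14 lines, 0.397 between the 3-factor and Blimp1 lines and 0.330 between the Blimp1 and Prdm14 lines. Each comparison uses the same 2 parental arrays, too few to split, so part of the excess may come from shared controls. Simulated unchanged lines with shared controls gave r of 0.5, which is not comparable with r in lines that changed. Their 0 shared calls cannot bear on the excess, since unchanged lines have few calls to share. The covariance of the changes was 0.2719, 0.1092 and 0.0816 for the 3 pairs in the order given, and 0.0261 in the simulations. The 3-factor, Blimp1 and Prdm14 lines each shared 1 call with the Tfap2c line. In each case it was Eif2s3y, which was already lower in all of these lines before doxycycline, in the Tfap2c line without a call.

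Direct tests set the line with all 3 factors against each single-factor line. Against the Prdm14 line Dppa3 was higher by 1.72 ± 0.28 (SE, limma adjusted p = 0.00319) and Hesx1 by 1.67, while Pou3f1, Dnmt3a and Dnmt3b were lower by 1.57, 1.45 and 1.27. Tfap2c and Nr0b1 differed by 0.76 and −0.71, without a call. The other Dnmt3a probe sets had 3-factor and Prdm14 means of 8.74 and 9.05, 9.14 and 10.97, 7.59 and 8.49, and 8.34 and 8.49. The size of the Dnmt3a difference thus depends on the probe set. Against the Blimp1 line Myc was higher by 3.44, Nr0b1 by 3.40, Dppa3 by 2.68 and Tdgf1 by 5.75 (adjusted p = 4.71e-13), and Foxd4, Podxl and Pou3f1 were lower by 4.67, 4.63 and 4.27. Against the Tfap2c line Tfap2c, Dppa3, Tcl1 and Hesx1 were higher by 5.63, 5.44, 5.28 and 4.72, with Tcl1 and Hesx1 below the filter level in the Tfap2c line. In these 3 tests 146, 905 and 983 genes were called. Upp1, Sema6a, Wt1 and Zc3h12a were lower than in the Prdm14 line, by 2.95, 2.72, 2.44 and 2.12, with Sema6a and Zc3h12a below the filter level in the 3-factor line. Fitted on their own 4 arrays, the comparison with the Prdm14 line called 0 genes by limma, although 865 had an adjusted p under 0.05 in the full model.

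The 3-factor line was also compared with the sum of the single-factor changes, to ask whether the factors add up. The calls were 125 genes, 82 above the sum and 43 below, out of 2138 with an unadjusted p under 0.05. Tdgf1 lay 5.62 above the sum, since its fall in the Blimp1 line was absent from the 3-factor line, and Foxd4 lay 5.92 below it. Dppa3 and Prdm1 departed by −0.89 and −0.10 and were not called (limma adjusted p = 0.497 and 0.907). Other germ-line and naive genes were called below the sum. Tfap2c, Ifitm1, Ifitm3 and Fbxo15 departed by −2.11, −2.06, −1.12 and −2.24 (limma adjusted p = 0.00225, 0.00249, 0.0292 and 0.00388). Eif2s3y, Uty and Erdr1 were also called above the sum, but their levels were already low in single-factor lines before doxycycline. Those of Eif2s3y and Uty lay below the filter level, so the size of the departure is not given. Mid1, Uba1y, H13, Slc38a4 and Ufsp2 were called above it too, and were lower in EpiLCs of a single-factor line. Has2, Nt5e and Pcdh8 fell in both the Blimp1 and Prdm14 lines, to below the filter level in the latter. They lay 3.47, 2.73 and 2.22 above the sum. Levels near background cannot fall by a full sum, so the split of 82 and 43 does not show whether the factors add up. Of 297 genes called in the 3-factor line and in neither the Blimp1 nor the Prdm14 line, 30 were also called in direct tests against both of those lines, 11 rising and 19 falling. Among them Rhox6 and Rhox9, X-linked homeobox genes of the germ line, rose by 3.31 and 3.21 against the parental line, Hey1 rose by 1.92, and the glucose transporter Slc2a1 fell by 1.30. Parental means of Rhox6 and Rhox9 lay below the filter level. Against the Prdm14 line Rhox6 was not called when any of the 4 arrays of that pair of lines was left out. The count of 125 was 53 without parental day 1 replicate 1, 83 without parental replicate 2, 83 without Blimp1 replicate 1 and 72 without Tfap2c replicate 1, and 66 after centring.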

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

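All tests in this part on the sex-linked genes and on Tdgf1 were chosen after the results were seen; the differences of changes themselves were planned.

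What stands out here is that the change from EpiLCs to day 1 differed between each of 3 lines and the parental line, tested as an interaction in limma. The counts were 972 genes in the 3-factor line, 336 in the Blimp1 line and 635 in the Prdm14 line. In the 3-factor line the pluripotency and germ-line genes Tcl1, Tfap2c, Dppa3 and Hesx1 rose by 5.71, 5.65, 5.53 and 4.72 more than in the parental line. Pcdh8, Pim2, Pou3f1 and Nt5e had changes lower by −5.45, −5.19, −5.00 and −4.84. In the Blimp1 line Foxd4, Pdzk1, Gprc5a and Tfap2c gained 6.19, 5.37, 4.29 and 3.65, and Tdgf1, Pcdh8, Chst15 and Bcl11b differed by −6.18, −4.45, −3.82 and −3.73. In the Prdm14 line Tcl1, Tfap2c, Epas1 and Lrrc31 gained 4.86, 4.85, 4.65 and 4.23, and Nt5e, Pim2, Wnt8a and Pcdh8 differed by −4.39, −4.36, −4.26 and −3.93. Tcl1, Tfap2c, Pcdh8, Pim2 and Nt5e are in more than 1 of these sets, with the same sign in each. Of the genes named, Tcl1, Hesx1, Pcdh8, Nt5e, Foxd4, Pdzk1, Gprc5a, Chst15, Bcl11b, Lrrc31 and Wnt8a had a group mean below the filter level of 3.95, so the sizes of their differences are approximate.

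Probe sets that the annotation assigns to no gene were outside the comparisons, and some of them changed as well. Of 4989 such probe sets that passed the filter, limma called 123 on day 1 in the 3-factor line, 47 in the Blimp1 line and 104 in the Prdm14 line. In EpiLCs the calls were 1, 7, 3 and 2 for the 3-factor, Blimp1, Prdm14 and Tfap2c lines, and 3 in the Tfap2c line on day 1. What they read was not examined.

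The Blimp1 line was low in 3 of 6 tested Y-linked genes and in Erdr1 and Mid1 before doxycycline was given. Induced Blimp1 is argued against as the cause, since the median change of the 3 well expressed Y-linked genes, Eif2s3y, Uty and Uba1y, was −5.61 in EpiLCs and their median interaction was −0.48. Loss of the Y chromosome in the clone is a candidate explanation, with each of these 3 genes lower at both stages and −2.52 the change nearest 0. The other 3, Kdm5d, Orly and Tspy-ps, changed by −0.76, −0.20 and −0.13 in EpiLCs without a call. Their parental means of 4.47, 5.48 and 4.95 are dim, so they decide little, and over all 6 genes the median change was −2.48 and the median interaction 0.45. Loss of 1 of 2 equal copies cannot account for Erdr1 and Mid1, which the reference table places on the X chromosome, since the smaller of their falls was −7.07. The Prdm14 line was lower in the same Y-linked genes by less, and a mixed population of cells was not tested.

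Tdgf1 on day 1 was low in the Blimp1 line and not in the 3-factor line, read at 1 probe set. A deletion or sequence difference at that probe set is argued against by its change of −0.08 in the Blimp1 line's EpiLCs. If induced Blimp1 acted whatever other factors are present, Tdgf1 would fall in the 3-factor line too. It changed there by −0.51, and the difference between the lines was called. This cannot decide the question, since the level of the Blimp1 transgene could not be read in either clone. A fall of the Nodal pathway may contribute and is not settled. The median of 14 pathway genes was −0.677 with camera adjusted p = 0.000481, but adjusted p = 0.259 with an estimated correlation, and the list was partly built from genes already seen to fall. Against it, the same list had medians of −0.58 and −0.51 in the 3-factor and Prdm14 lines (camera adjusted p = 0.0855 and 0.0473; adjusted p = 0.476 and 0.428 with an estimated correlation), where Tdgf1 changed by only −0.51 and 0.06.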

How the results depend on the processing

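Leaving out Y-linked genes, Erdr1 and Mid1 was chosen after the data were seen; the other alternatives were planned. Counts of called genes stayed within 1.5 times in 156 of their alternative values and moved in 62, and none of 295 named gene values changed sign, although 86 lost their call under at least 1 setting and 41 when an array was left out. Left-out arrays gave 1 to 12 genes for the Tfap2c line on day 1, 53 to 116 for the departure from the sum, 0 to 2 for the Tfap2c interaction, and in EpiLCs 1 to 10, 12 to 26, 5 to 16 and 3 to 9 for the 3-factor, Blimp1, Prdm14 and Tfap2c lines. Below, comparisons are with the parental line. With no limit on the change, counts were 4837 for the parental stages, 3846, 2411, 3347 and 12 for the 3-factor, Blimp1, Prdm14 and Tfap2c lines on day 1, 8, 33 and 9 for the first 3 in EpiLCs and 2616, 1213 and 1698 for their interactions. The 3-factor line then gave 3939, 865 and 4045 against the Blimp1, Prdm14 and Tfap2c lines and 204 for the departure, and shared calls were 1078, 2534, 791, 3, 5 and 3, because calls no longer needed a 2-fold change. Counted as probe sets, which are more numerous, the calls were 1551 for the parental stages, 1469, 1172 and 2 for the 3-factor, Prdm14 and Tfap2c lines on day 1, 4 and 18 for 3-factor and Blimp1 EpiLCs, and 1392 and 1575 for the 3-factor line against the Blimp1 and Tfap2c lines. With only the arrays compared, and so fewer samples, the counts were 142 and 0 for the Blimp1 and Tfap2c lines on day 1, 0, 3, 1 and 0 for the 4 EpiLC comparisons, 173 and 1 for the Blimp1 and Tfap2c interactions, 0 for the 3-factor against the Prdm14 line and 60 for the departure. By treat against 0.5, a stricter test, they were 233 and 1 for the Blimp1 and Tfap2c lines on day 1, 0, 6 and 2 for 3-factor, Blimp1 and Tfap2c EpiLCs, 114 and 394 for the Blimp1 and Prdm14 interactions, 53 against the Prdm14 line and 27 for the departure. The Tfap2c line on day 1 had 2 after quantile normalization, 1 after centring and 2 with probe sets averaged, which also gave 2 in its EpiLCs; centring gave 1 for 3-factor EpiLCs and 66 for the departure; the cause was not tested. Without a filter each line shared 2 calls with the Tfap2c line. Without sex-linked genes the EpiLC counts were 1, 6 and 2 for the 3-factor, Blimp1 and Prdm14 lines. Replicate numbers as a block gave 1 for 3-factor EpiLCs, and changed no other count by over 1.5 times. Deviations of same-numbered arrays correlated at −0.065 to 0.196 over 45 group pairs, and at −0.233 to 0.555 over 8993 genes of mean 6 or more, with 30 pairs above 0.1. Among the parental, Blimp1, Prdm14 and Tfap2c day 1 groups every pair lay between 0.211 and 0.555 over those genes. These groups thus share an effect by replicate number, which the main model leaves out. The numbers were not read as pairs, since not every pair of groups is above 0.1. The 3-factor day 1 group correlated with these groups at −0.233 to −0.008 over the same genes. The block setting fits 1 common replicate term to all arrays, so it cannot fully remove an effect that only some groups share. Gene list shifts went from 58 to 0 with an estimated correlation. A log offset was not run, since the table is already log2; lists and overlaps were recomputed only under their own alternatives. Dim genes limit the calls: residual SD was 0.457 at means under 4 and 0.057 above 10.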

Other observations

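The added lists and the test of the Tfap2c probe sets were chosen after the results were seen; the tests on the Tfap2c line's own change and on its slope were written before their results.

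Further groups of genes were tested as 9 added lists in 5 comparisons, 45 tests in all. Of these, 15 passed an adjusted p of 0.05 by camera and 0 with an estimated correlation, the lowest being 0.259. Enzymes of cholesterol synthesis were lower as a list in the 3-factor and Prdm14 lines on day 1, with medians of −0.45 and −0.45 over 17 genes and 0 called by limma (adjusted p = 2.07e-06 and 7.61e-06; adjusted p = 0.259 for each with an estimated correlation). The list was also lower in the Blimp1 line and from EpiLCs to day 1 in the parental line, where Ebp rose, with medians of −0.15 and −0.38 (adjusted p = 0.015 and 0.00098; adjusted p = 0.476 and 0.428 with an estimated correlation). Targets of ATF4, the transcription factor of the amino acid response, had a median of −0.65 over 19 genes in the Blimp1 line, 2 of them called (adjusted p = 1.75e-13; adjusted p = 0.259 with an estimated correlation). It was also lower in the parental stage change and in the 3-factor, Prdm14 and Tfap2c lines, with 1, 5, 4 and 0 genes that fell and medians of −0.49, −0.29, −0.25 and −0.07 (adjusted p = 0.000394, 0.00098, 0.04 and 0.0473; adjusted p = 0.581, 0.581, 0.789 and 0.789 with an estimated correlation). Ribosomal protein genes, 22 tested, had no call in any of the 5 comparisons by limma.

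Genes of axon guidance, which also steer cell adhesion and migration, were among the largest falls. In the 3-factor line Sema6a, Rtn4rl1 and Unc5b fell by 4.44, 4.05 and 3.13, although the list of 34 did not shift (camera adjusted p = 0.318) and 3 members rose, among them Ntn1 by 1.61. Cldn1, a tight junction gene, fell by 3.52 in the 3-factor line and 2.72 in the Prdm14 line, where the junction list gave camera adjusted p = 0.0294 and adjusted p = 0.27 with an estimated correlation. Among enzymes that build the extracellular glycan coat, a list of 25 that did not shift in the 3-factor, Blimp1 or Prdm14 line (camera adjusted p = 0.992, 0.692 and 0.992), 2, 3 and 2 genes were called. Has2, the hyaluronan synthase, fell by 3.57, 3.35 and 3.75 in these lines, and Hs6st2 by 3.95, 1.87 and 4.06. In retinoic acid metabolism the synthesis gene Aldh1a2 rose by 2.63, 3.38 and 2.02 in these lines, and the binding protein gene Crabp2 fell by 3.54 in the 3-factor line and 1.91 in the Prdm14 line. Of 14 retinoic acid genes 2, 2 and 2 rose and 3, 0 and 3 fell in the 3-factor, Blimp1 and Prdm14 lines. The list did not shift (camera adjusted p = 0.476, 0.838 and 0.762). The imprinted gene Peg3 rose in the same 3 lines, by 1.38, 1.45 and 1.28, and Peg12 by 2.80 and 2.20 in the 3-factor and Blimp1 lines; in the Prdm14 line both means of Peg12 lay below the filter level. Phlda2 rose by 1.23 in the Prdm14 line. Other imprinted genes fell, Nap1l5 and Rian in the 3-factor line and Nap1l5 in the Prdm14 line. Slc38a4 fell in the Blimp1 line, where it was lower by 0.89 before doxycycline. The list of 22 did not shift in the 3-factor, Blimp1 or Prdm14 line (camera adjusted p = 0.658, 0.344 and 0.476). In the Tfap2c line on day 1 the imprinted list shifted down and the axon guidance and Nodal pathway lists up (camera adjusted p = 0.0473, 0.0403 and 0.0473; adjusted p = 0.476, 0.428 and 0.428 with an estimated correlation). The only call among them, H13 at −1.72, was already lower by 1.61 before doxycycline. Sema6a, Rtn4rl1, Cldn1, Has2, Aldh1a2, Nap1l5 and Peg12 had a group mean below the filter level of 3.95 in at least 1 of these comparisons, so the sizes of their changes are approximate.

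Few genes were called in the Tfap2c line, and 3 explanations were tested. Poor arrays are argued against, since the line's own change from EpiLCs to day 1 called 854 genes against 921 in the parental line, 652 of them shared. That stage change is large in every line, so it cannot decide whether replicates were too few for smaller differences. In the self-test of this contrast, 45% of genes were called at a log2 change of 1, 2.5% at 0.5 and 87.5% at 1.5. A call needs a change of at least 1, so the shares at 1 and 0.5 are held down by that limit. They do not measure whether replicates were too few. The 3-factor response at a small size is argued against, since the slope of this line's changes on those of the 3-factor line was 0.007 ± 0.006 (SE) over called genes, within the −0.008 to 0.019 of 100 simulated unchanged lines and below 0.1. A transgene that was not expressed may explain the count, and cannot be told apart from a factor without effect at 24 h. The highest change over 3 Tfap2c probe sets was −0.40, and none of them rose only in lines that carry the Tfap2c transgene, so none reads it for certain.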
